A study of Mus musculus with 22 samples.

How the data were processed

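Gene expression was measured on Affymetrix MOE430A arrays, 1 array per sample, from 4 wild type, 5 premalignant and 13 malignant samples. Per the labels, RNA was labelled with biotin in 1 round of amplification, and the 13 lymphomas came from independent mice. The labels call the wild type and premalignant samples biological replicates but do not say that they came from separate mice. Their p-values therefore measure only the spread between these samples. The authors made the deposited values, which are intensities, with GCRMA, per the submitters' processing notes. GCRMA subtracts a background estimated from probe sequence, normalises arrays to a common distribution and summarises each probe set. Its version, and whether all 22 arrays were processed together, are not given in the sources used here. The values are on a linear scale, as their range shows, and log2 was taken here. All 22690 probe sets, controls included, were present for each of the 22 arrays.

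The table that pairs probe sets with genes gave 1 gene symbol for 20380 probe sets (89.8%), several for 691 and none for 1555, besides 64 control probe sets. 0 symbols changed when looked up by their Entrez identifier in the RefSeq gene table. Probe sets were kept when their log2 value exceeded 4 on at least 4 arrays, which left 10789. Of these, 9832 had 1 symbol and stood for 6437 genes, each tested through its probe set with the highest mean over all arrays. Other probe sets of the same gene were called in opposite directions for 3, 102 and 75 genes in the 3 comparisons. A group mean below log2 4 was set to that level before a fold was taken, and such folds are written as at least N-fold. No fold is given where both means lie below it. Control probe sets were left out of the tests. They served to compare the 3′ and 5′ ends of beta-actin and Gapdh and to centre arrays on the hybridisation spikes in 1 alternative.

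Each comparison was fitted on its own 2 groups with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with statmod 1.5.0. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Lists of genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, where at least 3 members were tested. The 24 pathway lists and the 10 cell type lists were adjusted apart. They hold 627 entries, of which 554 were on the array with 1 symbol and 452 were tested. The pathway lists were the Myc network, ribosome biogenesis, nucleotide synthesis, polyamine metabolism, glycolysis and lactate transport, oxidative phosphorylation, amino acid supply and ATF4 targets, protein folding and the unfolded protein response, DNA replication, mitosis, D-type cyclins and CDK inhibitors, p53 targets, the BCL2 family, the DNA damage response, DNA methylation and Polycomb, pro-B and pre-B cells, mature B cells, MHC class II, B cell receptor signalling, B lineage transcription factors, lysosome and autophagy, the interferon response, the NF-κB response, and adhesion and migration. The cell type lists held markers of T cells, natural killer cells, neutrophils and their precursors, monocytes and macrophages, erythroid cells, plasma cells, dendritic cells, platelets, and stroma and endothelium, and sex-linked transcripts.

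The order of changes was read from the overlap of calls, beside 100 simulated sets of unchanged arrays that shared the premalignant arrays in the same way. The spread among lymphomas was compared by permuting the array labels of group-centred values 100 times. Fold changes across genes were compared by their covariance as well as their correlation, and genes are not independent replicates. The groups, lists, tests, filter, threshold and most alternatives were chosen before the data were examined. So was the rule for named genes, which takes the members of the Myc network, the 5 largest increases and decreases by fitted log2 change whose groups overlap by at most 1 array, up to 3 called members of each list in its main direction and 1 in the other, the 10 genes with the largest SD among lymphomas, and Cdkn2a, Trp53, Mdm2 and Cdkn1a. The rule gave 92, 105 and 111 genes in the 3 comparisons, of which not all are named. Examples of a list were preferred where their call held without any single array, so that the named examples are steadier than the rest. Of the genes given by the rule 59, 58 and 13 are named in these comparisons, with 1, 4 and 0 more from outside it. Wfdc21, Cd4, Car2 and Slc4a1 in the first 2 comparisons were chosen after their values were seen. No probe set of Trp53 alone was named here, and it is not analysed here.

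The fits were tested on simulated data, in which 200 of 6437 genes were changed and the spread of each group was that of the real arrays. Of the genes changed 2-fold, 69%, 80% and 79% were recovered in the comparisons of premalignant with wild type, malignant with premalignant and malignant with wild type arrays, and of those changed 4-fold 98%, 97% and 94%. Of 6237 unchanged genes, 8, 38 and 23 were called, which made up 4.6%, 17.7% and 11.7% of all simulated calls. With a spread shared by the groups, these shares were 6.2%, 5.8% and 6.4%. With the own spread of each group, the simulated lymphoma comparisons thus held a larger share of false calls than the adjusted p threshold allows. The alternatives were no filter, a filter at log2 6, the mean over the probe sets of a gene, each probe set tested on its own, 1 fit over all 3 groups, group-wise array weights, a robust variance trend, median, quantile and spike centring, a 2-fold threshold, the replicate number as a block and leaving out 1 array at a time. Added after the data were examined were fits without the arrays of lowest correlation with their wild type and premalignant groups, fits without each malignant array and fits with the actin 3′ to 5′ difference as a covariate. The correlation of Cdkn2a with p53 targets was left out because Cdkn2a lay at the floor. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. For arrays no depth applies, and their number limits the precision.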

Results

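The series holds 22 Affymetrix MOE430A arrays of mouse B cells on the C57Bl/6 background. Mice with the Eμ-Myc transgene express Myc from an immunoglobulin heavy chain enhancer and develop B cell lymphoma. The arrays fall into 4 of wild type B cells, 5 of premalignant transgenic B cells and 13 of lymphomas from independent mice. Per the labels, B cells were isolated from bone marrow or spleen on magnetic beads carrying antibodies to B220 or IgM, and the tissue of each array is not given in the sources used here. The labels name wild type and premalignant cells as positive for B220, a B lineage surface marker, and name no marker for the lymphomas. Wild type and premalignant cells came from littermates 4 to 6 weeks old. The labels of the lymphomas carry the same age, which is not used here. The deposited values are GCRMA intensities, used here as log2, with 22690 probe sets per array. 6437 genes passed the filter on dim probe sets and were tested. The number of arrays per group limits the precision.

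The arrays separated by stage along the first principal component, which held 55.9% of the variance of the tested genes. Wild type arrays lay at -66.5 ± 2.78, premalignant arrays at -29.5 ± 7.82 and malignant arrays at 31.8 ± 7.52 on it (SD, n = 4, 5 and 13). The array controls for RNA quality differed in the lymphomas. The 3′ probe set of beta-actin exceeded the 5′ probe set by 0.77 ± 0.10 log2 units in wild type arrays, 0.70 ± 0.085 in premalignant arrays and 1.93 ± 0.37 in malignant arrays. The lowest malignant value was 1.29 and the highest of the other arrays was 0.86. The same difference for Gapdh was 0.45, 0.25 and 0.94 in the 3 groups. Wild type replicate 2 and premalignant replicate 1 had the lowest mean correlations with the other arrays of their groups, 0.956 and 0.938.

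**Figure D1:**
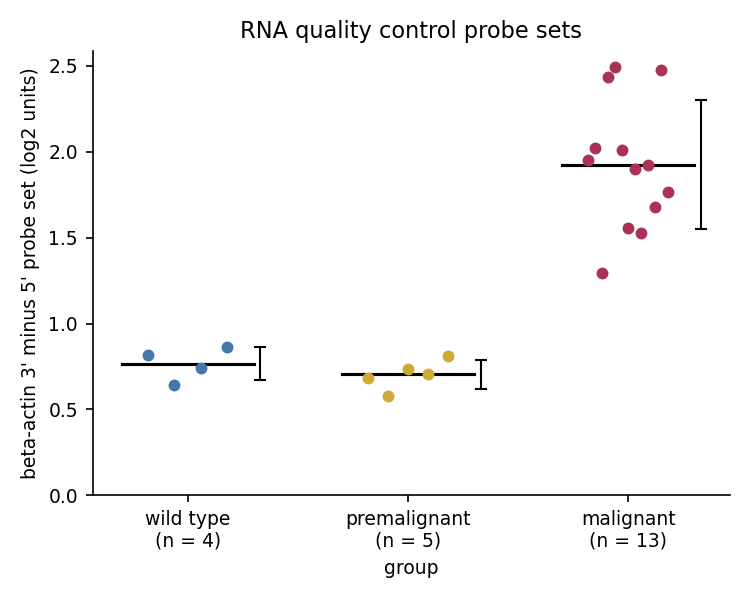
Difference between the 3′ and 5′ control probe sets of beta-actin (log2 units, y axis) in each array, by group (x axis), with the group mean as a bar and its SD as a whisker. The 13 malignant arrays lie between 1.29 and 2.49, above the wild type and premalignant arrays.

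The comparison of premalignant with wild type B cells asked what the transgene changes before lymphoma. Myc itself rose 7.59-fold (log2 9.97 ± 0.26 against 7.04 ± 0.27, SD, n = 5 and 4; limma adjusted p = 1.4e-05), and every premalignant array lay above every wild type array. 1725 of 6437 genes passed, 818 higher and 907 lower in premalignant cells, and 647 of them differed by at least 2-fold. Ranked by fitted log2 change among genes whose groups overlap by at most 1 array, the first 5 rises were those of Ptgr1, which reduces prostaglandins and leukotrienes (at least 19.0-fold, adjusted p = 1.4e-05), the branched-chain aminotransferase Bcat1 (at least 5.25-fold), the methyltransferase Smyd2 (at least 5.16-fold), the uridine-cytidine kinase Uck2 (at least 6.99-fold) and the mitotic kinase Aurkb (8.47-fold). The first 5 falls were those of the transcription factor Stat4 (at least 7.18-fold lower, adjusted p = 2.6e-05), the surface glycoprotein Cd200 (at least 3.55-fold lower), the heparan sulfate sulfotransferase Hs3st1 (at least 2.15-fold lower), the interleukin-21 receptor Il21r (5.77-fold lower) and the transcription factor Bhlhe40 (at least 1.98-fold lower). This rank counts values under the filter level, so that other genes can have larger folds than a bound given here.

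**Figure D2:**
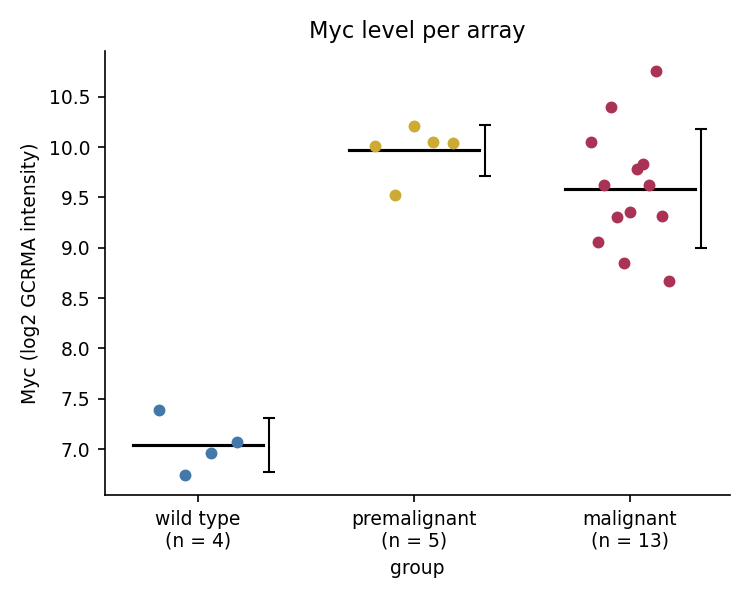
Log2 GCRMA intensity of Myc (y axis) in each array, by group (x axis), with the group mean as a bar and its SD as a whisker. The means are 7.04 in 4 wild type, 9.97 in 5 premalignant and 9.59 in 13 malignant arrays.

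Genes of cell division rose together in premalignant cells. Of the mitosis list, 24 of 26 measured members rose (24 adjusted over the list alone), with a median log2 change of 2.31 (camera adjusted p = 8.5e-18; adjusted p = 0.076 with an estimated correlation). With group means below the filter level set to it, the median was 2.11. Members that rose included the cyclin Ccna2 (7.79-fold) and the spindle checkpoint kinase Bub1b (7.62-fold). 24 of 28 DNA replication genes rose (25 adjusted over the list alone), including the origin loading factors Mcm10 (at least 4.37-fold) and Cdc6 (at least 6.41-fold; list adjusted p = 1.0e-13, and adjusted p = 0.089 with an estimated correlation). In the DNA damage response list 8 of 17 members rose (9 adjusted over the list alone), such as the uracil glycosylase Ung (at least 2.26-fold) and the recombination factor Rad54l (at least 1.62-fold; list adjusted p = 1.7e-04, and adjusted p = 0.089 with an estimated correlation).

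Genes that build ribosomes, nucleotides and amino acids rose as well. Ribosome biogenesis genes rose in 25 of 32 cases (28 adjusted over the list alone), led by Rrp1b (4.32-fold) and Wdr12 (3.94-fold; list adjusted p = 1.2e-13, and adjusted p = 0.063 with an estimated correlation). Nucleotide synthesis genes rose in 18 of 23 cases (18 adjusted over the list alone), led by the ribonucleotide reductase subunit Rrm2 (4.11-fold) and the folate enzyme Mthfd1 (3.67-fold; list adjusted p = 6.1e-11, and adjusted p = 0.063 with an estimated correlation). In the amino acid supply and ATF4 list 6 of 12 members rose and 2 fell (the same counts adjusted over the list alone). The serine synthesis enzyme Psat1 (4.79-fold), the leucine transporter Slc7a5 (4.61-fold) and the asparagine synthetase Asns (at least 2.05-fold) rose (list adjusted p = 0.0033, and adjusted p = 0.063 with an estimated correlation). In the glycolysis list 7 of 15 members rose and 2 fell (8 and 2 adjusted over the list alone), the lactate transporter Slc16a1 (6.71-fold) and the hexokinase Hk2 (at least 2.78-fold) being highest (list adjusted p = 0.014, and adjusted p = 0.348 with an estimated correlation). The spermidine synthase Srm rose 3.80-fold and was the only member of the polyamine list to pass.

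Smaller shifts were found in mitochondrial and chaperone genes. 6 of 27 oxidative phosphorylation genes rose (6 adjusted over the list alone), such as cytochrome c, Cycs (2.11-fold; list adjusted p = 2.4e-05, and adjusted p = 0.186 with an estimated correlation). 8 of 20 protein folding genes rose (9 adjusted over the list alone), among them the mitochondrial chaperonin Hspd1 (2.40-fold), and 1 fell (list adjusted p = 0.0092, and adjusted p = 0.335 with an estimated correlation). The DNA methylation and Polycomb list held members that went both ways, with Uhrf1 (7.99-fold) and Ezh2 (4.36-fold) higher and Ezh1 (at least 1.54-fold) lower (5 higher and 4 lower of 14; list adjusted p = 0.136).

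Genes of mature B cells were lower in premalignant arrays while several genes of early B cells were higher. The tissue of each array is not known here. A difference in tissue or in the mix of B cell stages was not tested and cannot be told apart from a change within cells. This holds for the genes of cell division as well. Of the mature B cell list 11 of 16 members fell and none rose (13 lower adjusted over the list alone), with a median log2 change of -1.06 (camera adjusted p = 5.0e-07; adjusted p = 0.063 with an estimated correlation). The low-affinity IgE receptor Fcer2a fell 4.87-fold and the complement receptor Cr2 fell 4.52-fold. 6 of 8 MHC class II genes fell (6 adjusted over the list alone), with the transactivator Ciita 3.56-fold lower (list adjusted p = 1.7e-04, and adjusted p = 0.063 with an estimated correlation). 15 of 19 B cell receptor signalling genes fell (19 adjusted over the list alone), by less, as with the co-receptor Cd72 (2.06-fold lower; list adjusted p = 7.8e-07, and adjusted p = 0.063 with an estimated correlation). 8 of 16 B lineage transcription factors fell (9 adjusted over the list alone), including Bcl6 (3.50-fold lower) and Foxo1 (2.30-fold lower; list adjusted p = 0.012, and adjusted p = 0.070 with an estimated correlation). 10 of 17 NF-κB response genes fell (10 lower and 1 higher adjusted over the list alone), led by Bcl3 (4.56-fold lower) and Nfkb2 (4.18-fold lower; list adjusted p = 2.4e-04, and adjusted p = 0.063 with an estimated correlation). In the pro-B and pre-B cell list 5 of 12 members rose (the same number adjusted over the list alone), such as the recombinase Rag1 (at least 4.23-fold) and the transcription factors Myb (4.54-fold) and Sox4 (4.53-fold; list adjusted p = 0.0036, and adjusted p = 0.187 with an estimated correlation). In 1 fit over all 3 groups, the MHC class II (adjusted p = 0.187), B lineage transcription factor (0.094) and pro-B and pre-B cell (0.066) lists did not pass.

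Of the remaining Myc network genes, Mnt, a repressor that competes with Myc for Max, fell 1.68-fold. The changes of Mycn (log2 -0.21), Mxd4 (-0.0064), Mga (-0.20) and Mlx (-0.24) did not pass, and neither did that of Mxd3 (0.51), which passed without wild type replicate 4 or premalignant replicate 1 (adjusted p = 0.028 to 0.043), as a mean over probe sets (0.021) and with group-wise array weights (0.048). Mxi1 rose 2.02-fold (adjusted p = 0.040) and Mlxip fell 1.30-fold (adjusted p = 0.043), but Mxi1 did not pass without wild type replicate 1, 3 or 4 or premalignant replicate 1, 2, 3 or 4 (adjusted p = 0.058 to 0.103) and Mlxip did not pass without wild type replicate 1, 2, 3 or 4 or premalignant replicate 2, 3 or 4 (adjusted p = 0.051 to 0.108). The Myc network list did not pass as a set (adjusted p = 0.701). Among 18 p53 targets Sesn1 (2.55-fold lower) and the peptide transporter Tap1 (2.04-fold lower) fell and the kinase Plk2 rose (at least 1.74-fold), the set did not pass (adjusted p = 0.479), and Mdm2 did not pass (log2 change -0.10). The survival factors Bcl2 (at least 1.61-fold lower) and Mcl1 (1.79-fold lower) were the called members of the BCL2 family (set adjusted p = 0.531). The kinase Cdk4 rose 2.56-fold within the cyclin D and CDK inhibitor list, where 4 of 11 members rose and 1 fell (set adjusted p = 0.101). 8 of 23 lysosome and autophagy genes fell, such as the cathepsin Ctsh (1.83-fold lower; list adjusted p = 0.023, and adjusted p = 0.216 with an estimated correlation), and this list did not pass without wild type replicate 4 (adjusted p = 0.056) or premalignant replicate 1 (adjusted p = 0.061), in 1 fit over all 3 groups (0.052) or with spike centring (0.079). The interferon (adjusted p = 0.147), adhesion (0.458) and polyamine (0.264) lists did not pass as sets. No marker list of another cell type passed in the fit as designed (plasma cell adjusted p = 0.673, monocyte and macrophage 0.673, stroma and endothelium 0.673). The neutrophil and granulocyte precursor markers had a median log2 change of 0.96 and an adjusted p of 0.053, which was 0.0048 without wild type replicate 2 and 0.048 without premalignant replicate 3. This list also passed without the filter (adjusted p = 0.049), with median centring (0.046), with spike centring (0.0070) and with the replicate number as a block (0.017), but not in 1 fit over all 3 groups (0.739) or with an estimated correlation (0.875). Without wild type replicate 2 and premalignant replicate 1, a setting chosen after the data were examined, 1705 genes passed, and the adjusted p was 0.0067 for the neutrophil list, 0.052 for the lysosome list and 0.055 for Plk2. Centring on the hybridisation spikes moved the median change of all genes from -0.054 to 0.20 log2 units and left 560 genes, 455 higher and 105 lower, against 818 and 907. Of the genes named, Sesn1, Bcl2, Foxo1, Ezh1, Cd72, Tap1, Ctsh, Mcl1, Mnt, Mxi1 and Mlxip did not pass after this centring (adjusted p = 0.052 to 0.897). In 1 fit over all 3 groups Cd72 (adjusted p = 0.157), Rag1 (0.135), Mnt (0.059) and Mlxip (0.202) did not pass, and with group-wise array weights Cd72 (0.107), Rag1 (0.089) and Mlxip (0.149) did not. Without the filter on dim probe sets Plk2 (0.062) and Mxi1 (0.110) did not pass and the interferon list did (0.045), and the DNA methylation list passed with spike centring (0.025).

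**Figure D3:**
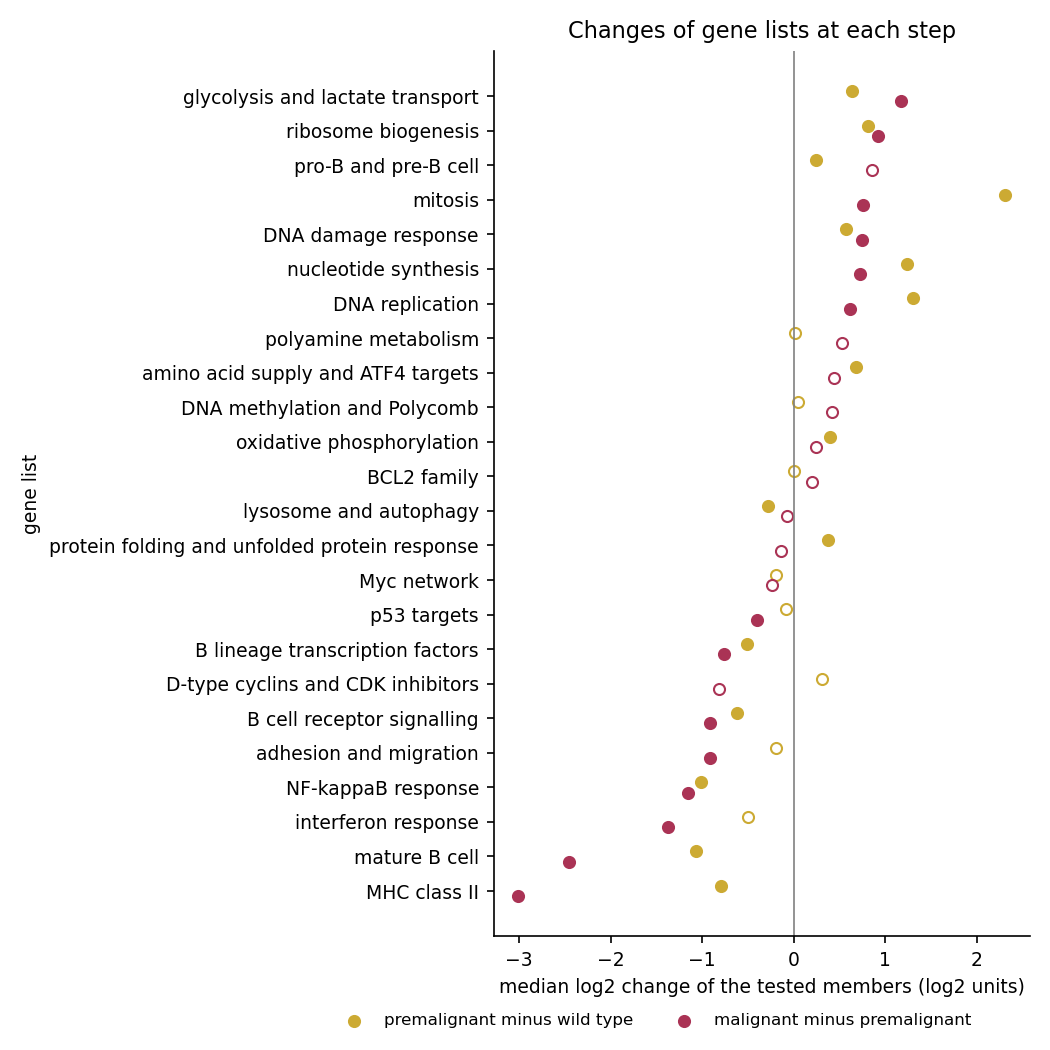
Median log2 change of each pathway list (x axis, log2 units) in premalignant against wild type arrays and in malignant against premalignant arrays, with lists on the y axis. Filled points passed camera at an adjusted p of 0.05 with the preset correlation, and open points did not. The mature B cell list has medians of -1.06 and -2.45.

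The comparison of lymphomas with premalignant cells asked what changes at the step to malignancy. 2711 of 6437 genes passed, 1597 higher and 1114 lower in lymphomas, and 844 differed by at least 2-fold. Myc did not pass (log2 change -0.38, adjusted p = 0.255). Mature B cell genes fell as a group. All 16 measured members fell (all of them adjusted over the list alone), with a median log2 change of -2.45 (camera adjusted p = 9.8e-15, and adjusted p = 0.0053 with an estimated correlation). The follicle homing receptor Cxcr5 (at least 21.8-fold lower), the activation marker Cd83 (at least 14.6-fold lower) and Cr2 (at least 13.2-fold lower) were at the floor of the array in lymphomas. In the same ranking as before, the first 5 falls were those of Fos (at least 80.3-fold lower, adjusted p = 6.9e-14), the immunoglobulin joining chain Jchain (at least 67.0-fold lower), the IgA heavy chain Igha (69.2-fold lower), Cxcr5 and the lymphoid surface protein Ly6d (59.8-fold lower). Probe sets for immunoglobulin and MHC genes can cross-hybridise.

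The beta-actin 3′ to 5′ difference of the arrays rose by 1.22 log2 units over the same step and so moved with all of the gene groups here. Antigen presentation and signalling genes fell with the mature B cell genes. 7 of 8 MHC class II genes fell (the same number adjusted over the list alone), including H2-DMb2 (24.4-fold lower) and H2-Oa (18.5-fold lower; list adjusted p = 1.2e-04, and adjusted p = 0.206 with an estimated correlation). 12 of 13 interferon response genes fell (the same number adjusted over the list alone), such as the transcription factor Irf9 (5.06-fold lower) and Ifi35 (3.53-fold lower; list adjusted p = 2.1e-08, and adjusted p = 0.042 with an estimated correlation). 12 of 17 genes of the NF-κB list fell (the same number adjusted over the list alone), but the leading members, Fos, Jun (at least 13.7-fold lower) and Junb (6.50-fold lower), are AP-1 subunits and immediate early genes (list adjusted p = 1.9e-08, and adjusted p = 0.0091 with an estimated correlation). 14 of 19 adhesion and migration genes fell (the same number adjusted over the list alone), among them the egress receptor S1pr1 (7.33-fold lower) and the homing receptor Ccr7 (6.91-fold lower; list adjusted p = 1.4e-07, and adjusted p = 0.0053 with an estimated correlation). 10 of 19 B cell receptor signalling genes (Blk, 5.57-fold lower; list adjusted p = 2.0e-05, and adjusted p = 0.077 with an estimated correlation) and 9 of 16 B lineage transcription factors fell (Spib, 4.17-fold lower; list adjusted p = 0.0011, and adjusted p = 0.077 with an estimated correlation). Adjusted over the list alone these counts were 10 and 10.

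Growth and division genes rose further in lymphomas. 30 of 32 ribosome biogenesis genes rose (the same number adjusted over the list alone), such as Ppan (2.89-fold) and the RNA polymerase I subunit Polr1a (2.90-fold; list adjusted p = 2.6e-11, and adjusted p = 0.077 with an estimated correlation). 12 of 15 glycolysis genes rose (the same number adjusted over the list alone), among them the pyruvate kinase Pkm (2.85-fold) and the lactate dehydrogenase Ldha (2.60-fold), and Hk1 fell 2.05-fold (list adjusted p = 3.4e-05, and adjusted p = 0.029 with an estimated correlation). Hk1 did not pass without premalignant replicate 2 (adjusted p = 0.085). 21 of 26 mitosis genes rose (22 adjusted over the list alone), such as Bub1b (2.67-fold) and the proliferation marker Mki67 (2.48-fold; list adjusted p = 7.8e-06, and adjusted p = 0.244 with an estimated correlation). 17 of 28 replication genes rose (19 adjusted over the list alone), such as the polymerase Pole (2.47-fold; list adjusted p = 1.2e-04, and adjusted p = 0.244 with an estimated correlation). 16 of 23 nucleotide synthesis genes rose, such as the mitochondrial folate enzymes Mthfd2 (2.78-fold) and Shmt2 (2.32-fold), and Prps2 fell 2.71-fold (the same counts adjusted over the list alone; list adjusted p = 0.0011, and adjusted p = 0.206 with an estimated correlation). In the DNA damage response list 9 of 17 members rose (10 adjusted over the list alone), such as the checkpoint kinase Chek1 (3.27-fold), and 1 fell (list adjusted p = 0.0072, and adjusted p = 0.206 with an estimated correlation).

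Measured targets of p53 were lower as a set in lymphomas. 8 of 18 measured p53 targets fell and 1 rose (the same counts adjusted over the list alone; list adjusted p = 0.011, adjusted p = 0.119 with an estimated correlation, and adjusted p = 0.419 without the filter on dim probe sets). The antiproliferative gene Btg2 fell 7.56-fold, Trp53inp1 fell 3.76-fold and Mdm2, which encodes the ubiquitin ligase of p53, fell 2.26-fold, while the nuclease gene Aen rose 2.73-fold. With the actin difference of each array as a covariate, Mdm2 (log2 change -0.46, adjusted p = 0.577) and Trp53inp1 (-1.89, adjusted p = 0.143) did not pass. Among cell cycle regulators the cyclin Ccnd1 rose 7.54-fold and Ccnd2 fell 5.04-fold, and the inhibitors Cdkn1b (2.21-fold lower) and Cdkn2d (2.45-fold lower) fell (list adjusted p = 0.087). In the Myc network Mxd4 (3.87-fold lower), Mlx (at least 1.69-fold lower) and Mxd3 (1.51-fold lower) fell and Mlxip rose (1.51-fold). Mycn fell with both group means under the filter level (log2 change -0.24, adjusted p = 0.041), but it did not pass without premalignant replicate 1, 3, 4 or 5 or malignant replicate 3, 5, 6, 7, 8, 10 or 13 (adjusted p = 0.050 to 0.127), after median (0.061) or quantile (0.304) centring or with a robust variance trend (0.053). In the fit as designed, 4 members fell and 1 rose of 9, and the list did not pass as a set (adjusted p = 0.237). In the protein folding list Pdia4 (6.45-fold lower) and Pdia3 (3.96-fold lower) fell and Hspd1 rose 1.99-fold, with 7 lower and 4 higher of 20, and the list did not pass (adjusted p = 0.087, 0.410 with an estimated correlation, and 0.047 without premalignant replicate 1). The lysosome (adjusted p = 0.565), BCL2 family (0.993), oxidative phosphorylation (0.103), DNA methylation (0.259), pro-B and pre-B cell (0.364), polyamine (0.129) and amino acid supply (0.141) lists did not pass as sets. Without the filter on dim probe sets the oxidative phosphorylation (adjusted p = 9.2e-05), polyamine (0.022), amino acid supply (0.039) and DNA methylation (0.025) lists passed. As means over probe sets the oxidative phosphorylation (0.032) and protein folding (0.046) lists passed, with spike centring the protein folding (0.047) and cyclin (0.041) lists, and with the replicate number as a block the cyclin list (0.013).

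Most measured markers of the stroma and endothelium list rose in the lymphoma arrays. Those that passed were Bgn, Col1a2, Col3a1, Cxcl12, Igfbp7 and Sparc, while the endothelial marker Pecam1 fell. 6 of 8 measured markers rose and Pecam1 fell 2.15-fold (log2 change 0.13 with the actin difference as a covariate), with a median log2 change of 4.22 (7 higher adjusted over the list alone; camera adjusted p = 2.3e-04, and adjusted p = 0.069 with an estimated correlation). With group means below the filter level set to it, the median was 3.38, and for the mature B cell list it stayed -2.45. In the same ranking, the first 5 rises were those of the matrix protein Sparc (at least 14.6-fold), the growth factor binding protein Igfbp4 (at least 15.3-fold), and the collagens Col3a1 (at least 17-fold), Col1a2 (at least 13.3-fold) and Col4a1 (at least 18.2-fold). Plasma cell markers fell in 5 of 7 cases (the same number adjusted over the list alone), led by Jchain (list adjusted p = 0.0020, and adjusted p = 0.069 with an estimated correlation). The lysozyme Lyz2 (6.87-fold) rose and the macrophage receptors Csf1r (2.89-fold lower) and Axl (2.52-fold lower) fell within the monocyte and macrophage list (adjusted p = 0.820). Of the lists with fewer than 3 measured members, the natural killer cell genes Gzma (at least 4.86-fold lower) and Nkg7 (log2 change -1.73, with both group means under the filter level) fell, the platelet gene Pf4 rose at least 1.64-fold, and the T cell gene Cd4 (log2 change 1.51) and the erythroid genes Car2 (-1.62) and Slc4a1 (-1.71) did not pass. Slc4a1 passed without premalignant replicate 2, 3, 4 or 5 (adjusted p = 0.016 to 0.047), but its change was -0.40 without premalignant replicate 2, whose value of log2 10.41 stood against 4.44 in the next array. No dendritic cell marker was tested. The neutrophil list did not pass (adjusted p = 0.884). Spike centring left 1771 genes, 1209 higher and 562 lower, and moved the median change of all genes from 0.089 to 0.22. Of the genes named, Mlx (adjusted p = 0.055), Hk1 (0.116), Mxd3 (0.118) and Mycn (0.766) did not pass after it. With the actin difference of each array as a covariate, added after the data were examined, 321 genes passed, 315 of them among the 2711. Of 58 named genes that passed here without it, 32 did not pass with it (adjusted p = 0.051 to 0.926). They were Axl, Blk, Bub1b, Ccnd1, Ccnd2, Ccr7, Cdkn1b, Cdkn2d, Chek1, Col1a2, Col3a1, Csf1r, H2-DMb2, H2-Oa, Hk1, Hspd1, Ly6d, Mdm2, Mki67, Mlx, Mlxip, Mthfd2, Mxd4, Mycn, Nkg7, Pdia3, Pecam1, Pf4, Pole, Polr1a, Shmt2 and Trp53inp1, with changes such as -1.13 for Blk, 2.98 for Ccnd1 and 1.96 for Col3a1. As a mean over probe sets Mlx did not pass (adjusted p = 0.211), and with the replicate number as a block Axl (0.072), Hk1 (0.068), Mlx (0.064), Mlxip (0.128) and Mycn (0.279) did not. For 102 genes, other probe sets of the same gene were called in the opposite direction, against 3 between premalignant and wild type arrays. The 102 include the list members Ncl (ribosome biogenesis), Kif11 (mitosis), Mcm3 (replication), Rrm1 (nucleotide synthesis) and Foxp1 (B lineage transcription factors). The list counts rest on 1 probe set per gene. Whether the actin difference of the lymphomas gave these opposite calls was not tested.

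**Figure D4:**
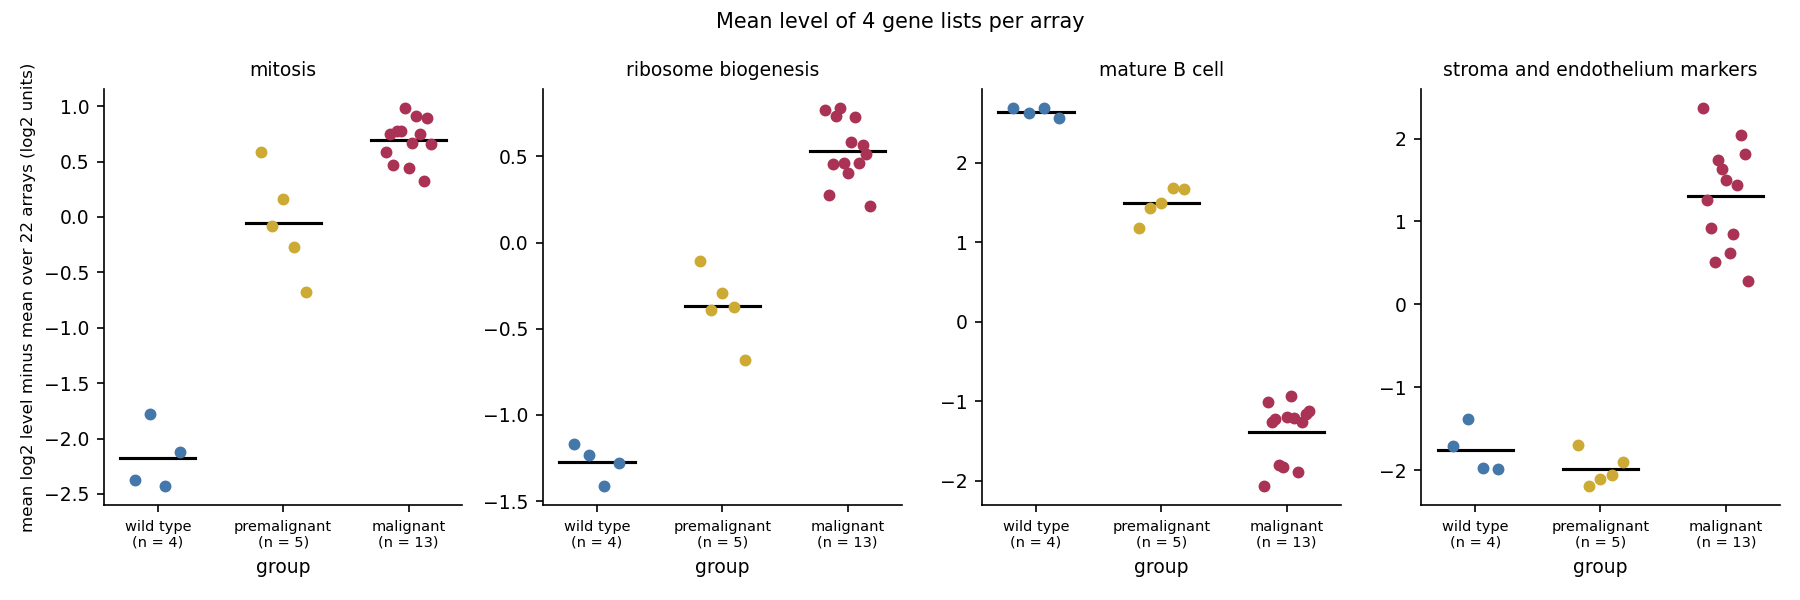
Mean log2 level of 4 gene lists in each array, relative to the mean over all 22 arrays (y axis, log2 units), by group (x axis). Points are arrays and bars are group means. The means in wild type, premalignant and malignant arrays are 2.64, 1.49 and -1.38 for the mature B cell list and -1.76, -1.99 and 1.31 for the stroma and endothelium list.

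The comparison of lymphomas with wild type cells spanned both steps. 3956 of 6437 genes passed, 2045 higher and 1911 lower, and 1989 differed by at least 2-fold. Myc was 5.83-fold higher (adjusted p = 5.9e-07). In the Myc network 2 of 9 members were higher, with Myc among them, and 3 lower (list adjusted p = 0.774). Ranked as before, the first 5 rises were those of Ptgr1 (at least 31.5-fold), Bcat1 (at least 20.9-fold), the metallothionein Mt1 (at least 27.7-fold), the fatty acid binding protein Fabp5 (at least 27.5-fold) and Igfbp4 (at least 15.3-fold). The first 5 falls were those of Jchain (at least 135-fold lower), Cxcr5 (at least 58.6-fold lower), Cr2 (at least 59.6-fold lower), the lymphotoxin Ltb (112-fold lower) and Cd83 (at least 48.2-fold lower). All measured genes of mitosis (26) and ribosome biogenesis (32) were higher, with medians of 2.99 and 1.61, and all of mature B cells (16), MHC class II (8) and the interferon response (13) were lower, with medians of -3.43, -3.64 and -1.69. With group means below the filter level set to it, these medians were 2.82, 1.61, -3.17, -3.64 and -1.24. The counts were unchanged when adjusted over the list alone. 21 of 27 oxidative phosphorylation genes rose (22 adjusted over the list alone; list adjusted p = 1.3e-04, and adjusted p = 0.084 with an estimated correlation). 14 of 24 pathway lists passed camera, and 11 did with an estimated correlation, where MHC class II (adjusted p = 0.263) and B lineage transcription factors (adjusted p = 0.084) no longer passed. Stroma and endothelium markers (adjusted p = 0.027, and adjusted p = 0.245 with an estimated correlation) were higher as a set, and plasma cell markers (adjusted p = 0.027, and adjusted p = 0.245 with an estimated correlation) were lower, though not without the filter on dim probe sets (adjusted p = 0.073). The erythroid markers Car2 (at least 4.44-fold lower) and Slc4a1 (at least 2.60-fold lower) fell, Car2 not without wild type replicate 2 (adjusted p = 0.063). The actin 3′ to 5′ difference of the lymphomas was higher here too, and as a covariate it left 1879 genes, without Car2 (adjusted p = 0.456) and Slc4a1 (0.179). Slc4a1 did not pass in 1 fit over all 3 groups (adjusted p = 0.051) or with the replicate number as a block (0.063). Spike centring moved the median change of all genes from 0.041 to 0.43 log2 units and the split to 2349 higher and 788 lower.

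The order of the changes was read from the overlap of the first 2 comparisons. Of the 1725 genes called between wild type and premalignant cells, 866 (50.2%) changed again in the same direction at the step to lymphoma, 85 (4.93%) in the opposite direction and 774 (44.9%) were not called. 450 genes rose at both steps and 416 fell at both, where independent lists of these sizes would share 203 and 157. The 2 comparisons share the premalignant arrays. In 100 simulated sets without any change no gene was called at both steps in the same direction. Those sets called only 17.4 and 13.7 genes on average at the 2 steps. Their overlap therefore gives no chance value for lists as long as those in the data. The mean correlation of fold changes across genes was -0.471 in the simulated sets, against 0.404 in the data. The covariance was 0.216 against -0.0288 simulated. With the premalignant arrays split between the comparisons, 256 to 688 genes repeated their direction and 7 to 21 turned over 20 splits. Among pathway lists, 23 of 32 ribosome biogenesis genes and 19 of 26 mitosis genes rose at both steps, and 11 of 16 mature B cell genes fell at both. In the interferon list 10 of 13 genes were called only at the step to lymphoma, a difference between steps that was not tested. A gene that turned with every group mean above the filter level, chosen after its values were seen, was Wfdc21 (log2 change 2.13 then -2.51).

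The spread among the 13 lymphomas was not shown to exceed that of the normal and premalignant cells over all genes. 3908 of 6437 genes (60.7%) had a larger SD among lymphomas than within the other groups, and the median ratio of the SDs was 1.16. Among 100 permutations of the array labels of group-centred values the mean share was 51.5% (permutation p = 0.208, one-sided). Without the filter on dim probe sets the share was 48.0%. The 8 MHC class II genes all had a larger SD among lymphomas, with a median ratio of 7.43, and the ratio was 3.87 for pro-B and pre-B cell genes and 0.618 for mitosis genes. The 10 genes with the largest SD included 7 genes of saliva or digestive secretion, Bpifa2 (SD 4.66), Amy1 (3.54), Smr3a (3.44), Chia1 (3.03), Dnase1 (2.92), Dcpp3 (2.83) and Car6 (2.81). Bpifa2, a parotid secretory protein, ranged from log2 2.38 to 12.79 and was above the filter level in 7 of 13 lymphomas, with means of 2.48 in wild type and 2.48 in premalignant arrays. The other 3 were the X inactivation transcript Xist (SD 4.27), the extracellular matrix protein Reln (3.24) and the immunoglobulin light chain segment Igkv9-120 (3.17).

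**Figure D5:**
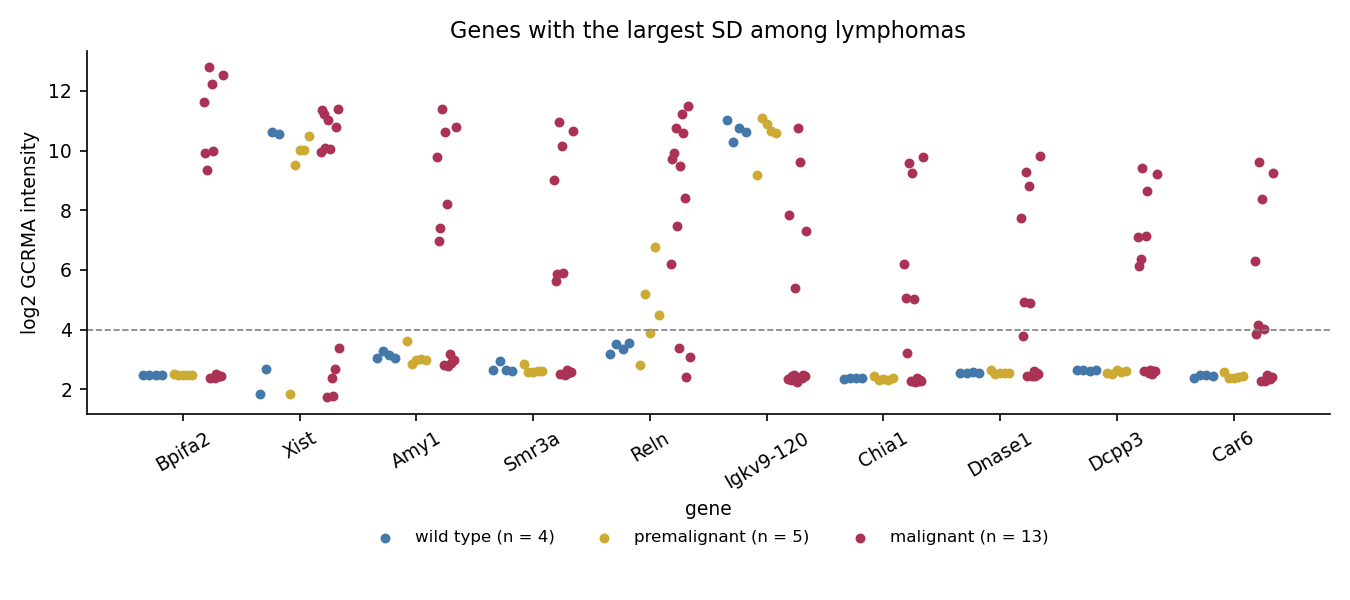
Log2 GCRMA intensity (y axis) of the 10 genes with the largest SD among lymphomas (x axis), one point per array, coloured by group. The dashed line is the filter level of 4. Bpifa2 spans 2.38 to 12.79 among the 13 malignant arrays.

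Cdkn2a, a tumour suppressor locus that restrains Myc through p53, stayed below the filter level in all 22 arrays, with 2.19 to 3.57 log2 units in lymphomas. Cdkn1a was above that level in 3 of 13 lymphomas and in none of the other arrays, and it was not tested. The planned correlation of Cdkn2a with p53 targets was not run, because values at the floor have no order.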

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

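Of the tests in this part, that of a lower share of B cells and the fit with the actin difference as a covariate were chosen only after the results had been seen. Markers of the stroma and endothelium list were higher in the lymphoma arrays, with a median log2 change of 2.27 against premalignant arrays over 12 markers without the filter. A lower share of B cells would raise the markers of every other cell type. Monocyte and macrophage markers changed by 0.14 (exact permutation p = 0.979) and so were not shown to rise. Plasma cell markers had the lowest change of the lists measured, -1.12 (exact permutation p = 1.2e-04, the smallest these groups allow). Plasma cells are of the B lineage, so their fall does not weigh against a lower share of B cells. Natural killer cell markers (-0.91, exact permutation p = 1.2e-04) and erythroid markers (-0.80, exact permutation p = 0.016) were lower too. In both lists 0 members had a mean over these arrays above the filter level, so their falls do not decide the question. The T cell (-0.09), dendritic cell (-0.09), platelet (-0.01) and neutrophil (0.36) lists changed less. Cells of stroma in the lymphoma samples remain a candidate explanation. The 6 markers that rose had a median pairwise r of 0.615 over the 13 lymphomas. This was above the 95th percentile of 0.235 among 1000 random lists matched on level. Less is shown for vessels, since the endothelial marker Pecam1 fell. Sparc (mean log2 7.86), Col3a1 (8.09) and Col1a2 (7.74) were above the filter level in all 13, and no gene of this list stands in another list used here. Selection on B220 or IgM beads would remove such cells. The labels do not say which bead each sample was selected with and name no marker for the lymphomas. Neither a difference in selection nor expression of these genes by lymphoma cells was tested.

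Fos (at least 80.3-fold lower) and Jun (at least 13.7-fold lower) fell in lymphoma arrays against premalignant arrays. A stress response to the handling of bead-selected normal and premalignant cells is a candidate explanation, since the 17 other handling-response genes tested had a median change of -1.38 (95% bootstrap interval over genes -2.90 to -0.69), or -1.27 with group means below the filter level set to it, with 12 lower and 0 higher. Zfp36 (-3.71), Ier2 (-1.38) and Jund (-1.10) were among those that fell, as was the heat shock gene Dnajb1 (-0.69), while the immediate early gene Egr1 (-0.70), Socs3 (-0.54) and the heat shock genes Hspa8 (0.13), Hsph1 (0.12) and, under the filter level, Hspa1b did not pass. Egr1, Junb, Nr4a1 and Nfkbia of this list are also in the NF-κB list, Ppp1r15a and Atf3 in the amino acid supply list and Hspa8 in the protein folding list. The handling explanation takes the lymphomas to have been handled in another way, which is not known here, since the labels name no marker for them. A loss of these genes that belongs to the lymphoma cells stays open and was not tested. Many of the genes that fell, such as Junb and Ier2, are immediate early genes like Fos and Jun. They could fall together under either explanation, so their median change does not tell these explanations apart.

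Mature B cell genes fell in lymphoma arrays by a median of 2.45 on the log2 scale against premalignant arrays. Dilution of B cell RNA by other cells, as the whole cause, would lower all B cell genes alike, but the mature B cell genes changed by -1.44 relative to 8 pan-B genes, whose median was -1.02 (exact permutation p = 0.045 over genes, which are not independent). Dilution as a part of the cause stays open, since the pan-B genes fell in the median too, ranging from -2.06 (Spib) to 0.32 (Ebf1). RNA of lower integrity cannot be told apart from the lymphoma group here. The slope of the mature B cell score on the actin 3′ to 5′ difference over the 13 lymphomas gives -0.25 for the group difference (95% interval -1.04 to 0.54), against an observed -2.87. But this slope is extended beyond the lymphomas, whose lowest actin difference was 1.29, to premalignant arrays, whose highest was 0.81, and so does not decide the question. With that difference as a covariate the median change went from -2.45 to -2.26 and 6 of 16 genes passed in place of 16, while the median SE rose from 0.31 to 0.58. The tissue of each array and the B cell stage from which each lymphoma arose stay open and were not tested.

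Splits of the arrays argue against chance in how they were assigned to groups for the 3 counts of genes, but do not exclude it. With 100 splits no share under 1 in 100 can be shown. The splits take the arrays as independent, which the labels do not show for wild type and premalignant samples. Only 1 of 100 splits of the arrays, the real one, gave as many genes in each comparison, with 1725 genes against at most 809 in another split for premalignant and wild type arrays, 2711 against 1008 for malignant and premalignant arrays and 3956 against 1512 for malignant and wild type arrays.

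Single arrays lay apart from their group by Dixon's ratio, the gap to the nearest array divided by the range of the group, in 23 of 314 tests in groups of 4 or 5. Chance alone gives about 1 in 20, here 15.7. Of the 23, 11 fell on premalignant replicate 1, 5 on wild type replicate 2 and 4 on premalignant replicate 2. Premalignant replicate 1 was the lowest for Xist (ratio 0.886, log2 1.85 against 9.51 in the next array), Igha (0.849), Cd83 (0.802), Igkv9-120 (0.746) and Csf1r (0.716), and the highest for Myb (0.746). This array alone in its group had a Y-linked transcript without Xist (Eif2s3y at log2 4.98), so its Xist flag reflects sex. It was also the highest, under the filter level, for Smr3a (0.870), Sparc (0.838), Amy1 (0.810), Hs3st1 (0.807) and Bpifa2 (0.721). Wild type replicate 2 was the highest for Cd200 (0.923), Col4a1 (0.904) and, under the filter level, Smr3a (0.940) and Cd4 (0.841), and its mean correlation with its group was the lowest (0.877). Premalignant replicate 2 was the highest for Slc4a1 (0.867, log2 10.41 against 4.44), for the plasma cell list mean (0.717) and, under the filter level, for Bcl2 (0.889) and Ezh1 (0.797). Premalignant replicate 5 was the highest, under the filter level, for Bhlhe40 (0.799), wild type replicate 1 the highest for Hk1 (0.888) and wild type replicate 3 the lowest for the adhesion list mean (0.930).

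Probe sets outside the comparisons by gene also changed. Of 508 kept probe sets with no gene listed, 105 passed between premalignant and wild type arrays, 219 between malignant and premalignant arrays and 309 between malignant and wild type arrays. Of 449 kept probe sets with several gene symbols, 100, 167 and 262 passed in the same comparisons.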

How the results depend on the processing

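The fits without wild type replicate 2 and premalignant replicate 1, those without each malignant array and those with the actin 3′ to 5′ difference as a covariate were chosen only after the data were examined. Counts are given for premalignant against wild type, malignant against premalignant and malignant against wild type, in that order, and the fits as designed gave 1725, 2711 and 3956 genes. With the added demand of a 2-fold change, which can only lower a count, 647, 844 and 1989 genes passed, and 218 genes were called at both steps in the same direction and 7 in opposite directions. Spike centring gave 560, 1771 and 3137 genes and raised the share of higher calls to 81.2%, 68.3% and 74.9%. The spike means were log2 9.64 ± 0.49, 9.38 ± 0.33 and 9.24 ± 0.35 in wild type, premalignant and malignant arrays (SD). This centring therefore raised the change of every gene by 1 constant per comparison and added the spread of the spikes between arrays. Why the spikes differed was not tested. Without the filter on dim probe sets, which raises the genes tested from 6437 to 12393, 4929 and 7921 genes passed in the lymphoma comparisons, most of them lower, the share of genes with a larger SD among lymphomas turned to 48.0%, and the change of Cd4 turned to -0.14 (the cause was not tested). With each probe set tested on its own, 4282 and 5987 of 9832 probe sets passed. Camera with an estimated correlation passed 0, 5 and 11 of 24 pathway lists, in place of 16, 14 and 14. At an unadjusted p under 0.05 it passed 11, 9 and 13, and fry, which does not compare a list with other genes, passed 21, 21 and 20 after adjustment. With the actin difference as a covariate, 321 and 1879 genes passed in the lymphoma comparisons. The covariate differs between lymphomas and the other arrays, and the median SE of the genes called without it rose from 0.18 to 0.36 and from 0.19 to 0.35, while their median absolute log2 change went from 0.77 to 0.65 and from 1.00 to 0.92.

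Each fit with the replicate number as a replicate block used only arrays whose number occurs in both groups, and 1418, 1677 and 2905 genes passed. Arrays of the same number share only that number: their deviations from the group means correlated at -0.11 to 0.21, and the own number was the best match in 1 of 4, 0 of 5 and 0 of 4 cases. Leaving out 1 array at a time gave 1292 to 1804, 2236 to 2739 and 3585 to 3978 genes and 15 to 16, 14 to 15 and 14 to 15 pathway lists. Among genes whose change did not pass between premalignant and wild type cells, Mdm2 ranged from -0.24 to 0.042 and Mxd4 from -0.12 to 0.13 over the arrays left out. Under spike centring the changes of Mdm2 (0.16), Mga (0.060), Mlx (0.022), Mxd4 (0.25) and Mycn (0.048) turned positive. Mxd4 was also 0.12 as a mean over probe sets, 0.024 without wild type replicate 2 and premalignant replicate 1 and 0.013 with the covariate. The covariate turned Car2 (0.023) and Pecam1 (0.13) positive in malignant against premalignant arrays. Spike centring adds the same amount to the change of every gene, which gave the turns under it. The cause of the other turns was not tested. None of the turned values passed.

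For the genes named in the text, 789 of 830, 808 of 861 and 176 of 181 values under the alternatives kept their direction and their side of the threshold. For pathway and cell type lists, 195, 202 and 206 of 224 did. The stricter filter, averaging probe sets, 1 fit over all 3 groups, group-wise array weights, a robust variance trend, median centring and repeated quantile normalisation left each count of genes within 1.5 times that of the fit as designed. Signal over background limits what can be seen, since 6437 of 12393 genes passed the filter and a gene below it in both groups has no fold. The planned correlation of Cdkn2a with p53 targets and its alternatives were not run.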

Other observations

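No test in this part was chosen only after its result was seen. Genes of early B cells differed from lymphoma to lymphoma. Igll1, a part of the surrogate light chain of pre-B cells, was above the filter level in 5 of 13 lymphomas and in none of the other arrays, with a highest value of log2 12.22. Vpreb1, its partner, was above it in 4 lymphomas, with a highest value of 10.62, and in none of the other arrays. Il7r, the receptor of a growth factor of early B cells, was above the level in 8 lymphomas and in 1 of 5 premalignant arrays. Rag1 was above it in 6 lymphomas, where it ranged from log2 3.09 to 8.97, in 5 of 5 premalignant arrays and in 0 of 4 wild type arrays. Rag2 was above it in 4 lymphomas and Dntt, a polymerase that adds nucleotides at the joints of antigen receptor genes, in 0. The extracellular matrix gene Reln was above it in 10 lymphomas, 3 premalignant and 0 wild type arrays.

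Neutrophil genes also had a wide range. The calcium-binding protein gene S100a8 lay between log2 2.79 and 11.09 in lymphomas and was above the filter level in 11 of them, and S100a9 was above it in 11. Their means were 5.40 and 5.62 in wild type arrays and 7.74 and 8.12 in premalignant arrays. The granule genes Camp and Mpo were above the level in 4 and 3 lymphomas and in none of the other arrays. Transcripts of the sex chromosomes divided the arrays, whose labels give no sex. Xist without a Y-linked transcript was found in 2 wild type, 4 premalignant and 8 malignant arrays, a Y-linked transcript without Xist in 2, 1 and 3, and neither in 2 lymphomas.

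The genes of salivary secretion with a large SD were high together in malignant replicates 1, 4, 6 and 13, with means over the 7 genes of log2 8.25, 10.43, 9.51 and 10.30, lower in replicates 2 (5.90), 3 (5.89) and 7 (6.66), and between 2.45 and 2.64 in the remaining 6. Salivary gland tissue in some lymphoma samples is a hypothesis formed from this pattern. Over the 13 lymphomas, 18 other salivary gland genes had a median r of 0.130 with the mean of the pattern genes, above the 95th percentile of -0.15 among 1000 random lists matched on level but below the bound set in advance, and most of these genes stayed under the filter level, where values have no order. Pip reached log2 9.13 (r = 0.927) and Cst10 7.98 (r = 0.895), each above the level in 4 lymphomas, and Klk1 reached 5.85 (r = 0.719), above it in 2. Bhlha15 reached 7.41 (r = -0.10), above the level in 3, and Krt18 4.97 (r = 0.047), above it in 2. The epithelial genes Krt8, Epcam and Cdh1 reached 2.55, 2.69 and 3.22. Selection on B220 or IgM beads would remove gland cells. Whether the lymphomas were so selected is not known here, since the labels name no marker for them. Some of the pattern genes are also expressed by other secretory glands, and gland tissue and expression by the lymphoma cells cannot be told apart here.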
